A study of Homo sapiens with 43 samples.

How the data were processed

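Total RNA of HOG cells was measured in 43 libraries of 14 groups. Per the labels' protocols, RNA was collected with a column kit with DNase digestion, and stranded libraries were prepared from total RNA as paired-end reads of 100 bp. The deposited values are integer counts per gene, 1 file per library with 58138 gene names each. They were made with STAR, SAMtools and HTSeq on hg38, per the submitters' processing notes, without versions. The annotation release and the strand setting of the counting are not given in the sources used here. Of the gene names, 94.5% were found in GENCODE release 29, which gave the coordinates. All 37 mitochondrially encoded genes stood at 0 counts in every library, so their share could not serve as a quality measure.

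Groups followed the labels. The labels name 5 sets, and fits were kept within them: set 1 (cuprizone, ethanol, untreated), sets 3 and 4 together (both ASOs at both labels, GFP ASO, untreated), the GFP ASO libraries of set 2 with those of sets 3 and 4, and set 5 (both alleles with DMSO or PRT4165). In each fit genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), counts were scaled by TMM, and group means were compared by quasi-likelihood F tests. This left 16729, 17504, 16167 and 15998 genes. A gene passed at a Benjamini-Hochberg adjusted p (FDR) under 0.05 within its comparison. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used. CPM beside a fold change were scaled by TMM within the fit. Those of the figure, of the cell markers and where so stated were taken on total counts, without TMM. Where a group had 2 libraries, or 1 library of 2 was left out, its spread was taken from the other groups of the fit.

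The groups, comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The 36 gene lists hold 747 genes chosen from general knowledge. Each list with 5 or more tested members was tested by camera of limma with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The size given with a list below is that of its tested members. Members past the threshold were counted over all genes tested and adjusted over the list alone. Of 507 list tests in the planned comparisons 154 passed with the preset, 21 with the estimated correlation, and 108 by fry. The last asks whether a list's genes move one way on balance. List tests of the comparisons added later are not in these counts.

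Named genes were taken as follows. Rule (a) took, of genes past the threshold with a mean of 5 CPM or more and every library of one group above every library of the other, the 10 with the largest fold change in each direction. It took 8 where several comparisons of a set were described together, and 5 against untreated, between sets and for the interaction. With 3 libraries against 3, chance alone separates 10% of genes so. Rule (b) took, in each list described, up to 4 members past the threshold with the smallest p, or the 1 with the smallest p if none passed. Rule (c) always took ATXN1, ATXN1L, CIC, BMI1, RING1 and RNF2 in set 5 and PTBP1, CTDSP1, SOX9 and LAMC1 in sets 3 and 4. Rule (d) took the 5 with the smallest p where fewer than 5 genes passed. Rule (e) took the 10 genes with a seed site and the largest mean change over both ASOs at 48h among those past the threshold in both, and found 0. Names of clones were passed over.

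For the microRNA sites, the 3' UTRs of GENCODE 29 were searched for GTGCCTT, the match to the seed AAGGCAC that both microRNAs share. Of 18824 genes with an annotated 3' UTR 2633 held a site, 533 of them the 8mer GTGCCTTA. Genes with a site were tested by camera against those without, and against 2091 genes matched on UTR length and GC content.

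The whole path was tested on simulated data with 200 changed genes, all with a mean of 5 CPM or more. Counts were drawn with the spread that genes of a like level had in the fit. No spread of single genes and no series of libraries was put in, so the shares recovered may not hold for the real libraries or for genes with few counts. At a log2 change of 0.5 it recovered 92.5% in cuprizone against ethanol, 94% in the miR-124 ASO at 48h, 91% in the GFP ASO against untreated, 97% between the GFP ASO groups, 91% in 85Q against 30Q and 73.1% in the interaction, and 100% in each at 1 and 2. Between 5 and 14 unchanged genes were called. A site effect of 0.1 put into simulated data came back as 0.1008, and 0 as 0.0069. The depth of 27.3 to 37.3 M counts per library placed counts on 21834 to 26401 genes, with 1.05 to 1.67% on the top gene EEF1A1 and 5.68 to 7.02% on the top 10. Between libraries of a group the counts spread more than counting alone gives (chi-square per degree of freedom 2.78 to 35 over 46 pairs, 0 of them identical).

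The alternatives were DESeq2, RLE scaling, no filter on low counts, a block for the replicate number, each library left out in turn, a fit of the compared groups alone, the set 2 GFP libraries as control, an estimated correlation, fry, 8mer sites alone and a matched background. The contrasts over both alleles and both treatments, the comparisons of 48h with 24W and the correction for gene span and GC content were added after the data were examined. Genes that share reads with copies were kept and are named as uncertain. No library was left out of the fits. Some genes are not reported here.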

Results

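HOG cells, a human line derived from an oligodendroglioma and used as a model of the oligodendrocyte, the myelin-forming cell of the brain, were profiled by sequencing of total RNA in 43 libraries. The series carried ideas from gene networks of mouse oligodendrocytes into these human cells. The libraries formed 14 groups in 5 labelled sets. Set 1 held cells given cuprizone, a copper chelator that demyelinates the brain of mice fed with it, cells labelled EtOH (ethanol) and untreated cells, with n = 3 in each group. Set 2 held 4 libraries of cells given an antisense oligonucleotide (ASO, a short synthetic strand that pairs with a chosen RNA) against GFP, a jellyfish protein without a human gene, labelled 48h. Sets 3 and 4 held ASOs against the microRNAs miR-124 and miR-506, each labelled 48h or 24W (n = 3 in each group), 4 GFP ASO libraries with no time label and 2 untreated libraries. What 24W stands for is not given in the sources used here. Set 5 held cells with a plasmid for ATXN1, the protein whose longer glutamine repeat causes a spinocerebellar ataxia, with 30 or 85 glutamines (30Q and 85Q), given DMSO or PRT4165, an inhibitor of the Polycomb ubiquitin ligase of RING1 proteins and BMI1 (n = 3 in each group).

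The total on genes ran from 27.3 to 37.3 M (mega) counts per library. By group it was 28.1 to 34.2 M with cuprizone, 27.8 to 32.4 M with ethanol, 31.3 to 32.5 M in untreated set 1, 31.1 to 34.2 M with the GFP ASO at 48h and 28.7 to 36.3 M with the GFP ASO of sets 3 and 4. It was 30.7 to 36.1 M and 31.8 to 34.4 M with the miR-124 ASO at 48h and 24W, 27.3 to 37.2 M and 29.7 to 34.5 M with the miR-506 ASO, and 28.4 to 32.5 M in untreated set 4. In set 5 it was 28.6 to 35.3 M and 29.8 to 37.3 M for 30Q with DMSO and PRT4165, and 30.7 to 33.9 M and 32.3 to 33.7 M for 85Q. The cells expressed the myelin genes MBP (mean 41.2 CPM, counts per M counts) and CNP (51.8) and the RNA-binding regulator of myelin QKI (115). The lineage factors OLIG2 (0.00367) and SOX10 (0.00219) were near 0. VIM (2230), an intermediate filament of mesenchymal and immature glial cells, and the keratins KRT8 (349) and KRT18 (300) were abundant, and 0 of 13 microglial markers reached a mean of 1 CPM over all libraries. Nothing in the labels states that the libraries of a group came from separate cultures, so every p-value below measures only the spread between these libraries. A value after a gene is its log2 fold change ± standard error.

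**Figure D1:**
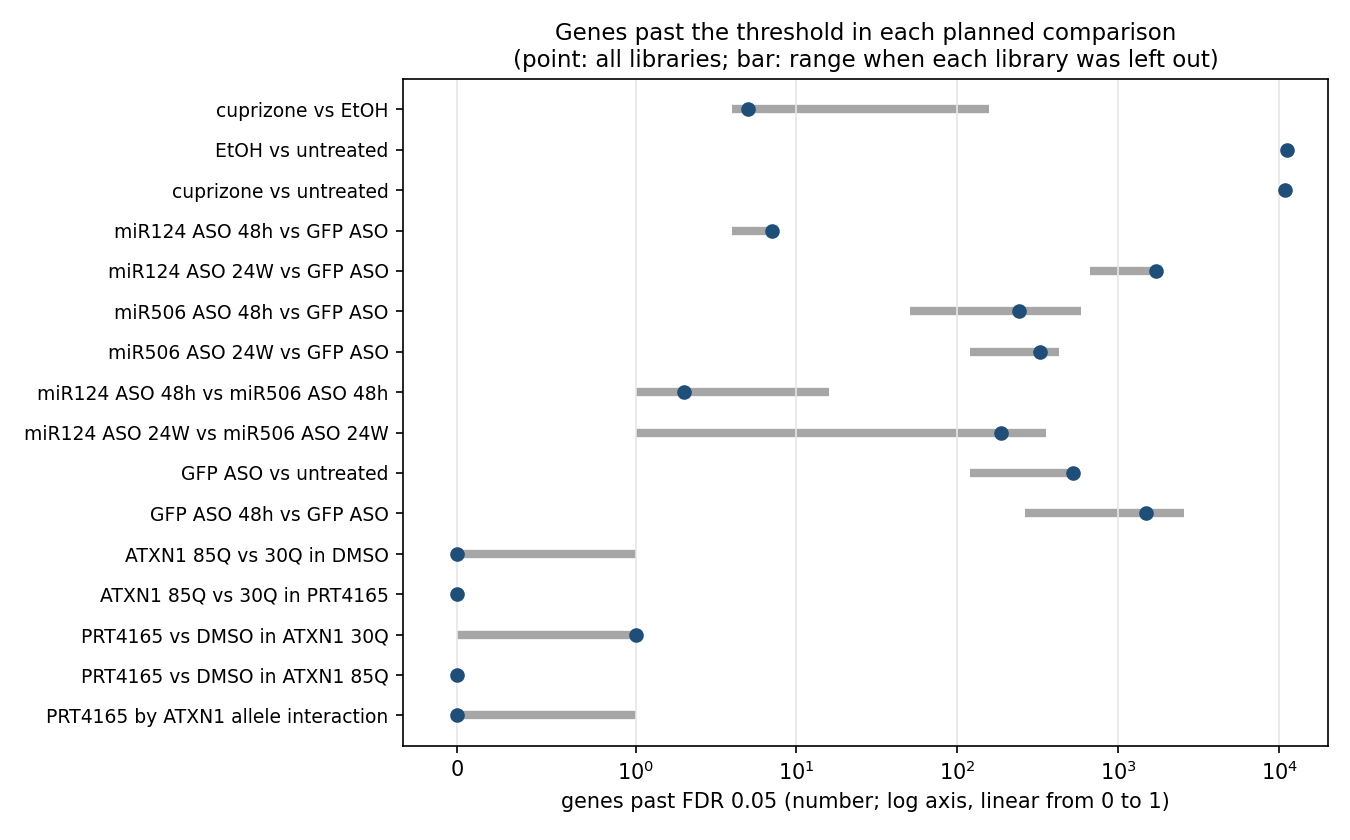
Number of genes past an FDR of 0.05 in each planned comparison (log axis, linear from 0 to 1), higher and lower together, with a grey bar for the range when 1 library is left out. Ethanol against untreated reached 11211 genes, and 85Q against 30Q in DMSO reached 0.

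Cuprizone against ethanol asks what the copper chelator changes in these cells beyond the EtOH treatment, taken here as its vehicle, which the labels do not state. Of 16729 genes 1 was higher and 4 were lower. CYP1B1 (chromosome 2, 38066973 to 38109902) fell from 199 ± 12.7 to 108 ± 5.04 CPM (-0.88 ± 0.06, n = 3 against 3). CYP1A1 (chromosome 15, 74719542 to 74725610) fell from 11.4 ± 1.35 to 4.91 ± 0.207 CPM (-1.22 ± 0.14). Both encode cytochrome enzymes that oxidize aromatic compounds and estrogens. TIPARP (-0.48 ± 0.06), an ADP-ribosylating enzyme, and SHISA2 (-0.65 ± 0.09), a membrane protein that holds back Wnt and FGF receptors, also fell. SGK1 (0.41 ± 0.06), a kinase that controls ion channels, rose. Of 14 copper handling genes 0 passed, 0 adjusted over the list alone (median 0.00, camera adjusted p = 0.936). CCS (0.19 ± 0.07), the copper chaperone of superoxide dismutase, had their smallest p. Of 12 mature oligodendrocyte genes 0 passed, 0 adjusted over the list alone (median 0.01, camera adjusted p = 0.611). CNP (0.21 ± 0.09) had theirs. Of 14 targets of YAP and TEAD, factors of the Hippo pathway, 0 passed, 2 higher adjusted over the list alone (median 0.11, camera adjusted p = 0.0233, adjusted p = 0.958 with an estimated correlation). ANKRD1 (0.49 ± 0.11) was foremost, and no other list passed here. The test was edgeR quasi-likelihood with Benjamini-Hochberg adjustment, and 1889 genes lay below an unadjusted p of 0.05 where chance gives 836. Without cuprizone library 2 the count was 158 (134 higher, 24 lower), so most called genes were then higher. DESeq2 called 19 genes (7 higher, 12 lower), the fit without a count filter 238 (172 and 66), and RLE scaling 4 (0 higher, 4 lower), with SGK1 lost. SGK1 and SHISA2 also lost their call without single libraries.

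Ethanol and cuprizone were each set against the untreated cells of set 1, to ask what the treatments changed from the resting state. Both differed from untreated in most genes. NGFR (chromosome 17, 49495293 to 49515017), the low-affinity neurotrophin receptor, rose from 1.04 ± 0.122 to 147 ± 26.8 CPM with ethanol (7.14 ± 0.17, n = 3 against 3). With cuprizone it stood at 152 ± 13.3 CPM (7.19 ± 0.17). PMEPA1 (5.02 ± 0.18), an inhibitor of TGF-beta signalling, the ubiquitin ligase RNF150 (5.89 ± 0.20) and the kinase STK32A (5.12 ± 0.18) rose with ethanol. With cuprizone they rose by 4.96 ± 0.18, 5.65 ± 0.20 and 5.01 ± 0.18. The antisense transcript MTUS2-AS1 rose from 0.532 ± 0.101 to 17 ± 6.14 CPM with ethanol and by 4.98 ± 0.40 with cuprizone. It is uncertain, as the strand setting of the counting is not given in the sources used here. The polo-like kinase PLK2 (-3.69 ± 0.12), the interleukin-7 receptor IL7R (-3.77 ± 0.18), the Wnt antagonist DKK1 (-3.32 ± 0.22) and the cell cycle repressor E2F8 (-3.01 ± 0.14) fell with ethanol. PLK2 (-3.44 ± 0.12), IL7R (-3.64 ± 0.17), E2F8 (-2.86 ± 0.14) and POLE2 (-2.88 ± 0.09), a subunit of DNA polymerase epsilon, fell with cuprizone. PSG1 (-2.95 ± 0.15), a pregnancy glycoprotein whose close copies may share its reads, fell too, by -3.28 ± 0.16 with cuprizone.

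Genes of the integrated stress response, which cells switch on when amino acids or protein folding fail, rose together. With ethanol, of 26 members 25 rose, 25 adjusted over the list alone (median 1.95, camera adjusted p = 3.42e-27, adjusted p = 0.00577 with an estimated correlation). With cuprizone, of 26 members 25 rose, 25 adjusted over the list alone (median 1.80, camera adjusted p = 1.3e-28, adjusted p = 0.00671 with an estimated correlation). ASNS (2.69 ± 0.11), which makes asparagine, CHAC1 (3.41 ± 0.11), which degrades glutathione, and PSAT1 (2.04 ± 0.08) of serine synthesis rose with ethanol. Genes of DNA replication fell as a whole. With ethanol, of 20 replication genes 20 fell, 20 adjusted over the list alone (median -1.66, camera adjusted p = 4.51e-35, adjusted p = 0.00577 with an estimated correlation). With cuprizone, of 20 replication genes 20 fell, 20 adjusted over the list alone (median -1.70, camera adjusted p = 8.34e-37, adjusted p = 0.0077 with an estimated correlation). The helicase subunits MCM7 (-2.37 ± 0.06), MCM4 (-2.16 ± 0.05) and MCM3 (-2.10 ± 0.06) and the methylation factor UHRF1 (-2.74 ± 0.09) were among them. Of 21 proliferation genes 21 fell, 21 adjusted over the list alone (median -1.12, camera adjusted p = 6.31e-16, adjusted p = 0.14 with an estimated correlation). UBE2C (-1.63 ± 0.06), CDC20 (-1.45 ± 0.07) and the kinase AURKB (-1.36 ± 0.06) led with ethanol. Of 16 replication-dependent histones, which share reads with copies, 16 fell, 16 adjusted over the list alone (median -1.91, camera adjusted p = 9.93e-25, adjusted p = 0.109 with an estimated correlation). Of 24 proteasome subunits 24 fell, 24 adjusted over the list alone (median -0.91, camera adjusted p = 7.47e-13, adjusted p = 0.109 with an estimated correlation). PSMC4 (-1.18 ± 0.06), an ATPase of its cap, fell. Of 29 nuclear genes of the respiratory chain 28 fell, 28 adjusted over the list alone (median -0.66, camera adjusted p = 1.67e-09, adjusted p = 0.223 with an estimated correlation). CYC1 (-1.63 ± 0.09) and UQCRC2 (-0.95 ± 0.06) serve its cytochrome c steps. Of 24 cholesterol genes 1 rose and 20 fell, 1 and 20 adjusted over the list alone (median -0.50, camera adjusted p = 0.000972, adjusted p = 0.478 with an estimated correlation). ACAT2 (-1.12 ± 0.08), FDPS (-1.06 ± 0.06) and LSS (-1.10 ± 0.08) fell, while the late-step enzyme SC5D (1.07 ± 0.07) rose. With cuprizone the medians of these 5 lists were -1.11, -1.80, -0.92, -0.63 and -0.46.

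Other lists lay higher with ethanol. Of 21 lysosome and autophagy genes 16 rose and 3 fell, 16 and 3 adjusted over the list alone (median 0.40, camera adjusted p = 0.000742, adjusted p = 0.284 with an estimated correlation). The autophagosome proteins GABARAPL1 (2.10 ± 0.12) and MAP1LC3B (1.57 ± 0.08) rose. Of 19 interferon-induced genes 12 rose and 4 fell, 13 and 4 adjusted over the list alone (median 0.61, camera adjusted p = 0.00938, adjusted p = 0.223 with an estimated correlation). IFIT2 (2.67 ± 0.12) and IFIT3 (2.44 ± 0.10) rose, and OAS3 (-0.91 ± 0.07), which makes an antiviral messenger, fell. Of 19 targets of Capicua, a repressor that ATXN1 binds, 14 rose and 2 fell, 14 and 2 adjusted over the list alone (median 0.68, camera adjusted p = 0.00196, adjusted p = 0.223 with an estimated correlation). SPRY4 (1.48 ± 0.11), ETV5 (1.23 ± 0.07) and DUSP6 (1.05 ± 0.08), which act in or below MAP kinase signalling, rose. Of 45 developmental regulators silenced by Polycomb 28 rose and 2 fell, 28 and 2 adjusted over the list alone (median 0.44, camera adjusted p = 0.00211, adjusted p = 0.289 with an estimated correlation). DLX2 (2.40 ± 0.16) and HOXB9 (1.87 ± 0.07) rose. With ethanol, of 12 tested mature oligodendrocyte and myelin genes, from a list of 30, 5 rose and 1 fell, 5 and 1 adjusted over the list alone (median 0.30, camera adjusted p = 0.0526). The myelin gene MBP rose by 1.28 ± 0.10 and 1.27 ± 0.10 with ethanol and cuprizone, TPPP (2.29 ± 0.10) and GPR37 (1.80 ± 0.15) rose, and CNP (-0.59 ± 0.09) fell. edgeR quasi-likelihood called 11211 genes with ethanol (5728 higher, 5483 lower, 67% of those tested) and 10943 with cuprizone (5663 and 5280, 65.4%). At least 2-fold, 2228 and 2202 genes rose and 1262 and 1090 fell. The TMM factors were 1.0529 to 1.0606 with ethanol, 1.0664 to 1.0823 with cuprizone and 0.8811 to 0.8832 in untreated set 1. TMM takes most genes as unchanged, which may not hold with 67% called. Small changes and the balance of higher and lower genes therefore depend on this scaling. All 10 named genes kept their call in each comparison whichever library was left out.

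**Figure D2:**
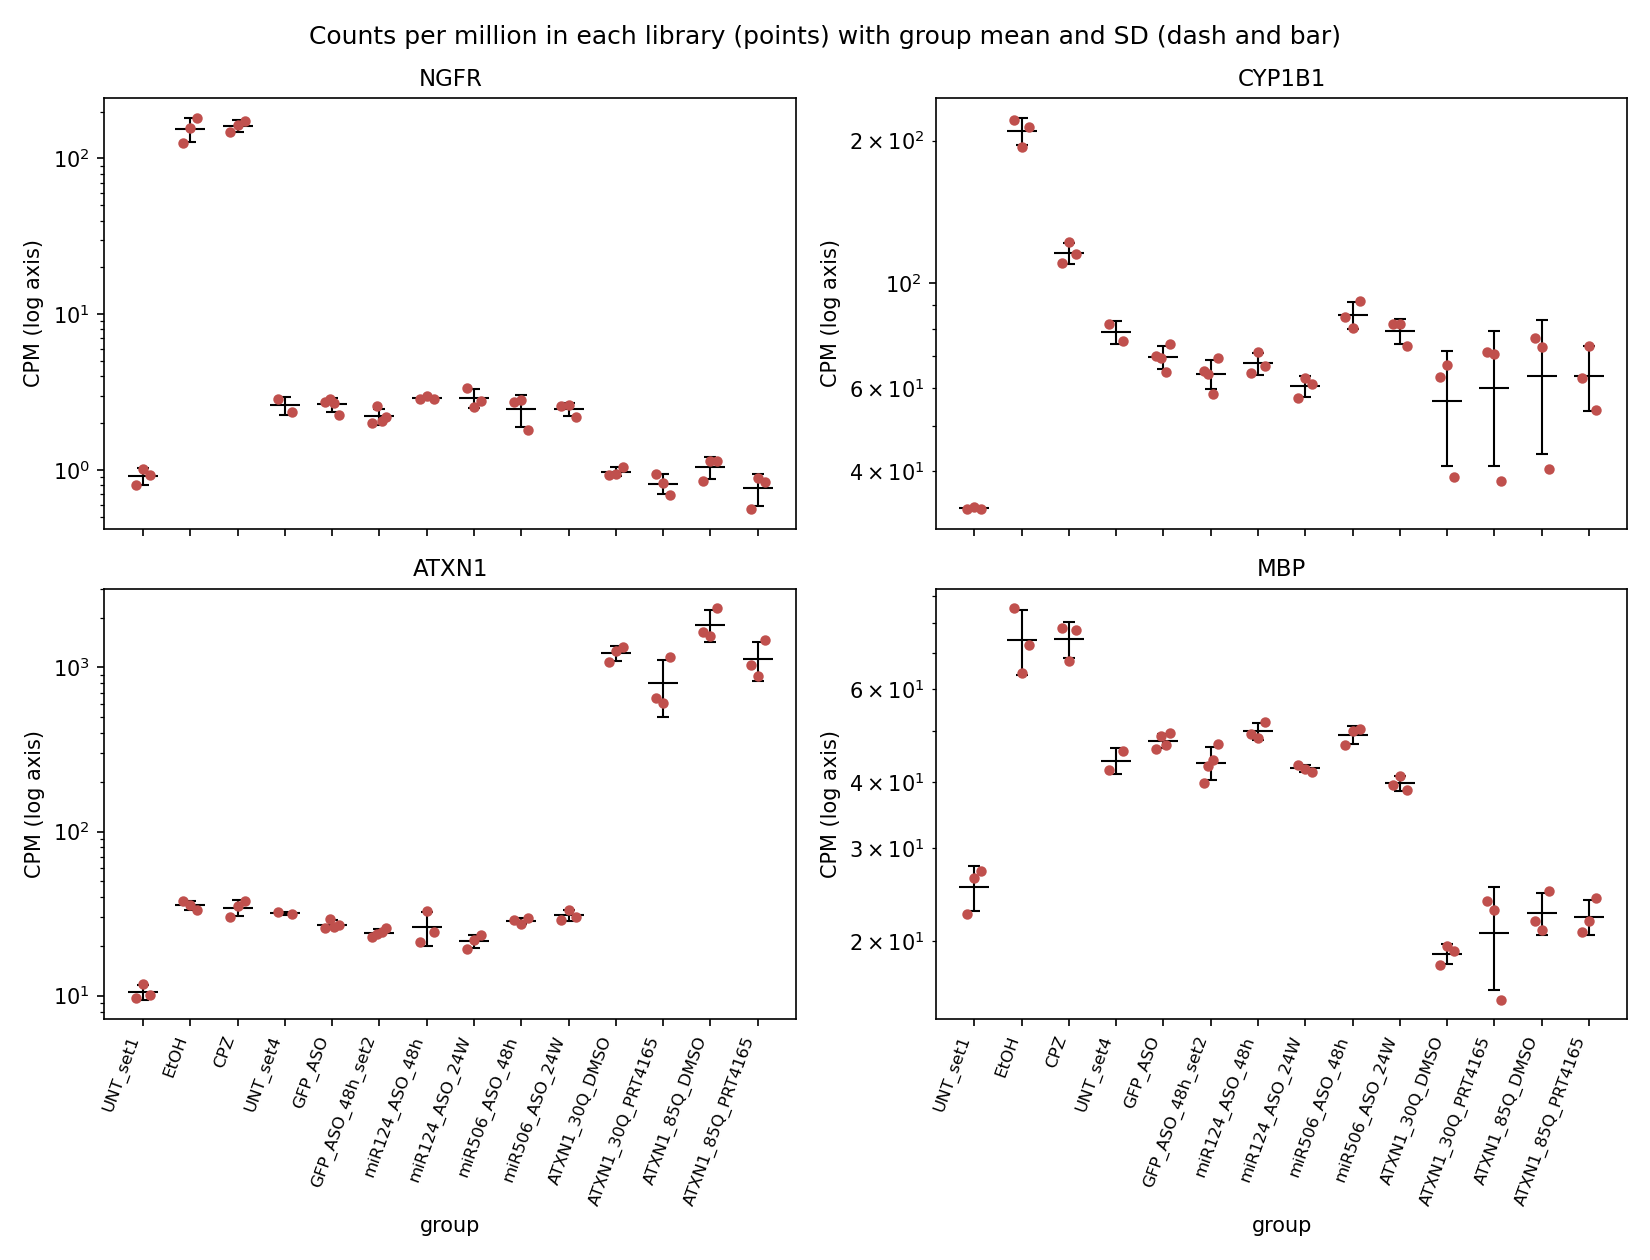
CPM (without TMM) of NGFR, CYP1B1, ATXN1 and MBP in every library (log axis), with the mean ± standard deviation of each of the 14 groups. NGFR stood at 155 ± 28.2 CPM with ethanol and 162 ± 14.5 with cuprizone, and ATXN1 was highest in the plasmid groups.

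The miR-124 ASO at 24W was set against the GFP ASO, to ask what an ASO against this microRNA, abundant in neurons, changes in the cells. The genes MIR124-1, MIR124-2, MIR124-3 and MIR506 had 0 counts in all 14 groups. Total RNA counts may miss microRNAs, so neither their presence in these cells nor their loss is shown. Genes of cholesterol synthesis rose, among them HMGCS1 (0.62 ± 0.09) and IDI1 (0.60 ± 0.06), enzymes of the mevalonate pathway (n = 3 against 4). SERPINB2 (0.72 ± 0.11), an inhibitor of plasminogen activators, WISP2 (0.66 ± 0.15), a secreted matrix protein, SAP30 (0.61 ± 0.09), part of a histone deacetylase complex, and PFKFB4 (0.61 ± 0.16), a regulator of glycolysis, rose too. With the GFP ASO against untreated cells of set 4, WISP2 was lower, opposite to its rise here, and SERPINB2 higher. ANKRD37 (0.70 ± 0.20) and the histone HIST1H2BB (0.65 ± 0.11), which shares reads with copies, also rose. IL1B (chromosome 2, 112829751 to 112836903), an inflammatory cytokine, fell from 112 ± 31.7 to 60.4 ± 3.47 CPM (-0.89 ± 0.14). It was also lower in the set 2 GFP ASO libraries against these same 4 GFP libraries, so it differed between control libraries too. The hedgehog factor GLI3 (-0.94 ± 0.19), the paraspeckle RNA NEAT1 (-0.84 ± 0.17) and the transcription factor ONECUT2 (-0.78 ± 0.19) fell. ZNF862 (-0.87 ± 0.13), THSD4 (-0.77 ± 0.09), the dynein DNAH1 (-0.78 ± 0.17) and LINC01355 (-0.80 ± 0.16) fell as well.

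Of 24 cholesterol genes 20 rose, 20 adjusted over the list alone (median 0.36, camera adjusted p = 1.28e-28, adjusted p = 0.00144 with an estimated correlation). INSIG1 (0.57 ± 0.06), which senses sterols, and HSD17B7 (0.53 ± 0.07) were among them. Of 17 genes of the unfolded protein response 12 rose, 13 adjusted over the list alone (median 0.25, camera adjusted p = 6.05e-11, adjusted p = 0.0164 with an estimated correlation). MANF (0.38 ± 0.06), HYOU1 (0.30 ± 0.06) and the chaperone CALR (0.28 ± 0.05) rose. Of 21 proliferation genes 18 rose, 20 adjusted over the list alone (median 0.38, camera adjusted p = 9.85e-29, adjusted p = 0.0162 with an estimated correlation). KIF20A (0.52 ± 0.06) and BUB1 (0.46 ± 0.06), which act in mitosis, rose. Of 20 DNA replication genes 7 rose, 16 adjusted over the list alone (median 0.24, camera adjusted p = 8.49e-09, adjusted p = 0.243 with an estimated correlation). RRM2 (0.40 ± 0.07) makes deoxynucleotides. Of 16 histone genes 15 rose, 15 adjusted over the list alone (median 0.38, camera adjusted p = 1.74e-16, adjusted p = 0.0867 with an estimated correlation). Of 24 proteasome subunits 22 rose, 23 adjusted over the list alone (median 0.30, camera adjusted p = 2.19e-22, adjusted p = 0.0576 with an estimated correlation). PSMC1 (0.37 ± 0.06) was one. Of 29 respiratory chain genes 16 rose, 24 adjusted over the list alone (median 0.21, camera adjusted p = 2.19e-12, adjusted p = 0.102 with an estimated correlation). NDUFB8 (0.34 ± 0.07) belongs to complex I. Of 18 hypoxia genes 8 rose, 10 higher and 1 lower adjusted over the list alone (median 0.31, camera adjusted p = 5.64e-05, adjusted p = 0.347 with an estimated correlation). EGLN3 (0.39 ± 0.09) encodes an oxygen-sensing enzyme. Of 25 reported targets of miR-124, which a loss of it would raise, 1 fell, 1 adjusted over the list alone (median 0.05, camera adjusted p = 0.658). The member that fell was SOX9 (-0.67 ± 0.17), a glial transcription factor. The splicing repressor PTBP1 (0.05 ± 0.07), the phosphatase CTDSP1 (0.12 ± 0.11) and the laminin LAMC1 (-0.09 ± 0.06) did not pass. edgeR quasi-likelihood called 1722 of 17504 genes (1082 higher, 640 lower). The count was 732, 682 and 666 without miR-124 libraries 1, 2 and 3 and 923 and 809 without GFP libraries 2 and 4, and ANKRD37, ONECUT2, PFKFB4 and WISP2 lost their call in some. It was 3274 in a fit of the 2 groups alone and 2012 without a count filter (858 higher, 1154 lower). After a correction for gene span and GC content it was 2978 (2252 higher, 726 lower).

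The miR-506 ASO at 24W against the GFP ASO asks the same of a microRNA that shares the seed of miR-124. Again the GFP ASO libraries carry no time label, so ASO and label cannot be told apart. IL1B fell here as well (-1.18 ± 0.15, n = 3 against 4), with the chemokine CXCL1 (-0.66 ± 0.10), the urokinase PLAU (-0.73 ± 0.06) and the anticoagulant receptor THBD (-0.78 ± 0.17). VEPH1 (-0.76 ± 0.13), THSD4 (-0.66 ± 0.09), ZNF862 (-0.66 ± 0.13) and the metallothionein MT1X (-0.66 ± 0.15), whose copies share reads, fell. WISP2 (1.04 ± 0.15), the immediate early factor EGR1 (0.61 ± 0.13) and PPME1 (0.57 ± 0.09), a phosphatase methylesterase, rose. The collagen COL5A2 (0.56 ± 0.09), the interferon-induced IFIT1 (0.52 ± 0.08), EID3 (0.57 ± 0.12) and the long noncoding HELLPAR (0.54 ± 0.14) rose. Of 19 genes of NF-kB signalling and inflammation 7 fell, 10 adjusted over the list alone (median -0.31, camera adjusted p = 8.22e-14, adjusted p = 0.0108 with an estimated correlation). ICAM1 (-0.37 ± 0.07) and CXCL8 (-0.44 ± 0.09) fell. IL1B, CXCL1, CXCL8 and THBD were also lower, and PPME1 higher, in the set 2 GFP ASO libraries against these same 4 GFP libraries. These genes thus differed between control libraries too, which differ in set and time label. CXCL8 was higher, and WISP2 lower, with the GFP ASO than in untreated cells of set 4, opposite to their changes here. Of 19 Capicua targets 3 fell, 4 adjusted over the list alone (median -0.17, camera adjusted p = 2.57e-06, adjusted p = 0.0032 with an estimated correlation). DUSP6 (-0.42 ± 0.07) and SPRY2 (-0.37 ± 0.08) restrain MAP kinase signalling. SPRY2 was higher with the GFP ASO than in untreated cells of set 4. Of 5 metallothionein genes 2 fell, 2 adjusted over the list alone (median -0.27, camera adjusted p = 0.00115, adjusted p = 0.0181 with an estimated correlation). MT2A (-0.59 ± 0.10) was the other. Of 24 cholesterol genes 9 rose, 20 adjusted over the list alone (median 0.23, camera adjusted p = 3.89e-22, adjusted p = 0.0032 with an estimated correlation). INSIG1 (0.46 ± 0.06) and IDI1 (0.41 ± 0.06) rose. Of 15 fatty acid synthesis genes 2 rose, 5 adjusted over the list alone (median 0.10, camera adjusted p = 0.000273, adjusted p = 0.00912 with an estimated correlation). SCD (0.30 ± 0.07) desaturates fatty acids. Of 21 proliferation genes 15 rose, 21 adjusted over the list alone (median 0.32, camera adjusted p = 2.51e-34, adjusted p = 0.00535 with an estimated correlation). KIF20A (0.45 ± 0.06) and BUB1 (0.35 ± 0.06) rose. Of 17 genes of the unfolded protein response 2 rose, 8 adjusted over the list alone (median 0.14, camera adjusted p = 3.52e-07, adjusted p = 0.0282 with an estimated correlation). MANF (0.29 ± 0.06) was one. Of 18 antioxidant genes of the NRF2 list 2 rose, 5 adjusted over the list alone (median 0.07, camera adjusted p = 0.000556, adjusted p = 0.0123 with an estimated correlation). TXNRD1 (0.34 ± 0.06) reduces thioredoxin. Of 25 reported miR-124 targets 0 passed, 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.583). PTBP1 (0.04 ± 0.07), CTDSP1 (0.07 ± 0.11), LAMC1 (-0.07 ± 0.06) and SOX9 (-0.30 ± 0.17) did not pass. edgeR quasi-likelihood called 327 of 17504 genes (177 higher, 150 lower). The count was 169, 138 and 148 without GFP libraries 2, 3 and 4 and 120, 204 and 158 without miR-506 libraries 1, 2 and 3, and EGR1, EID3, HELLPAR, MT1X, THBD and ZNF862 lost their call in some. It was 554 by DESeq2, 574 without a count filter and 664 after the span and GC correction.

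At 48h the miR-124 ASO changed few genes against the GFP ASO. FOS (chromosome 14, 75278774 to 75282230), an immediate early transcription factor, rose from 7.39 ± 0.924 to 14.1 ± 1.26 CPM (0.93 ± 0.10, n = 3 against 4). PABPC1L (0.43 ± 0.08), a poly(A)-binding protein, rose and the dynein light chain TCTE3 (-0.52 ± 0.10) fell. The small RNAs SNORD3B-1 (0.81 ± 0.15) and SCARNA15 (-0.67 ± 0.10) share reads with copies and are uncertain. Of 19 immediate early genes 1 rose, 7 higher and 1 lower adjusted over the list alone (median 0.20, camera adjusted p = 7.78e-11, adjusted p = 0.0103 with an estimated correlation). Of 14 YAP and TEAD targets 0 passed, 4 higher adjusted over the list alone (median 0.13, camera adjusted p = 2.44e-05, adjusted p = 0.0722 with an estimated correlation). CTGF (0.31 ± 0.08), a matrix growth factor, had their smallest p. These targets lay lower with the GFP ASO than in untreated cells of set 4. Of 25 reported miR-124 targets 0 passed, 0 adjusted over the list alone (median 0.00 but mean -0.01 and tested as higher, camera adjusted p = 0.798). SOX9 (-0.30 ± 0.17), PTBP1 (-0.01 ± 0.07), CTDSP1 (-0.01 ± 0.11) and LAMC1 (0.06 ± 0.06) did not pass. edgeR quasi-likelihood called 7 genes (5 higher, 2 lower), with 912 below an unadjusted p of 0.05 against 875 by chance. The count was 4 without GFP library 1, 2 or 4 or miR-124 library 3, and of the 5 named genes FOS alone kept its call throughout. It was 15 by DESeq2, 89 without a count filter (25 higher, 64 lower) and 2117 against the 4 GFP libraries of set 2, where SOX9 stood at 0.13.

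At the same label WISP2 (1.24 ± 0.15) and FOS (from 7.39 ± 0.924 to 14.8 ± 1.59 CPM) were higher with the miR-506 ASO than with the GFP ASO (n = 3 against 4). WISP2 was lower, and SERPINB2 and DNA replication genes higher, with the GFP ASO than in untreated cells of set 4, opposite to their changes here. For these a shift of the control cannot be told apart from an effect of the miR-506 ASO. EGR1 (0.65 ± 0.13), the matrix protein TGFBI (0.66 ± 0.11), the glycoprotein GPNMB (0.65 ± 0.13), the vasodilator peptide ADM (0.63 ± 0.15) and the nuclear envelope protein SUN3 (0.79 ± 0.13) rose. The chemokine CXCL3 (-0.64 ± 0.14), SERPINB2 (-0.62 ± 0.13), the aminopeptidase ANPEP (-0.49 ± 0.10) and MYEOV (-0.50 ± 0.08) fell. SH3TC2 (-0.64 ± 0.11), DPF1 (-0.60 ± 0.14), NAT8L (-0.48 ± 0.12) and the uncertain SCARNA15 (-0.60 ± 0.10) fell too. Of 19 immediate early genes 2 rose, 3 higher and 1 lower adjusted over the list alone (median 0.10, camera adjusted p = 0.0701). Of 18 NRF2 list genes 1 rose, 3 adjusted over the list alone (median 0.13, camera adjusted p = 0.00345, adjusted p = 0.0744 with an estimated correlation). TXNRD1 (0.28 ± 0.06) rose. Of 20 DNA replication genes 1 fell, 12 adjusted over the list alone (median -0.23, camera adjusted p = 1.41e-07, adjusted p = 0.743 with an estimated correlation). TYMS (-0.22 ± 0.06) makes thymidylate. Of 19 Capicua targets 2 fell, 5 adjusted over the list alone (median -0.09, camera adjusted p = 0.00619, adjusted p = 0.0744 with an estimated correlation). ETV4 (-0.35 ± 0.09) and DUSP5 (-0.29 ± 0.07) fell. Of 25 reported miR-124 targets 1 rose, 1 adjusted over the list alone (median -0.06, camera adjusted p = 0.924). CAV1 (0.26 ± 0.05) rose, while PTBP1 (-0.21 ± 0.07), CTDSP1 (-0.22 ± 0.11), SOX9 (-0.23 ± 0.17) and LAMC1 (0.11 ± 0.06) did not pass. edgeR quasi-likelihood called 242 genes (148 higher, 94 lower). The count was 65, 51 and 121 without GFP libraries 1, 2 and 4 and 590 and 54 without miR-506 libraries 2 and 3, and FOS, MYEOV, SCARNA15, SH3TC2, SUN3, TGFBI and WISP2 kept their call throughout. It was 11 in a fit of the 2 groups alone, 711 by DESeq2, 826 without a count filter (336 higher, 490 lower) and 5086 against the GFP libraries of set 2, where SH3TC2 (0.01), TXNRD1 (-0.04) and SOX9 (0.18) changed direction.

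**Figure D3:**
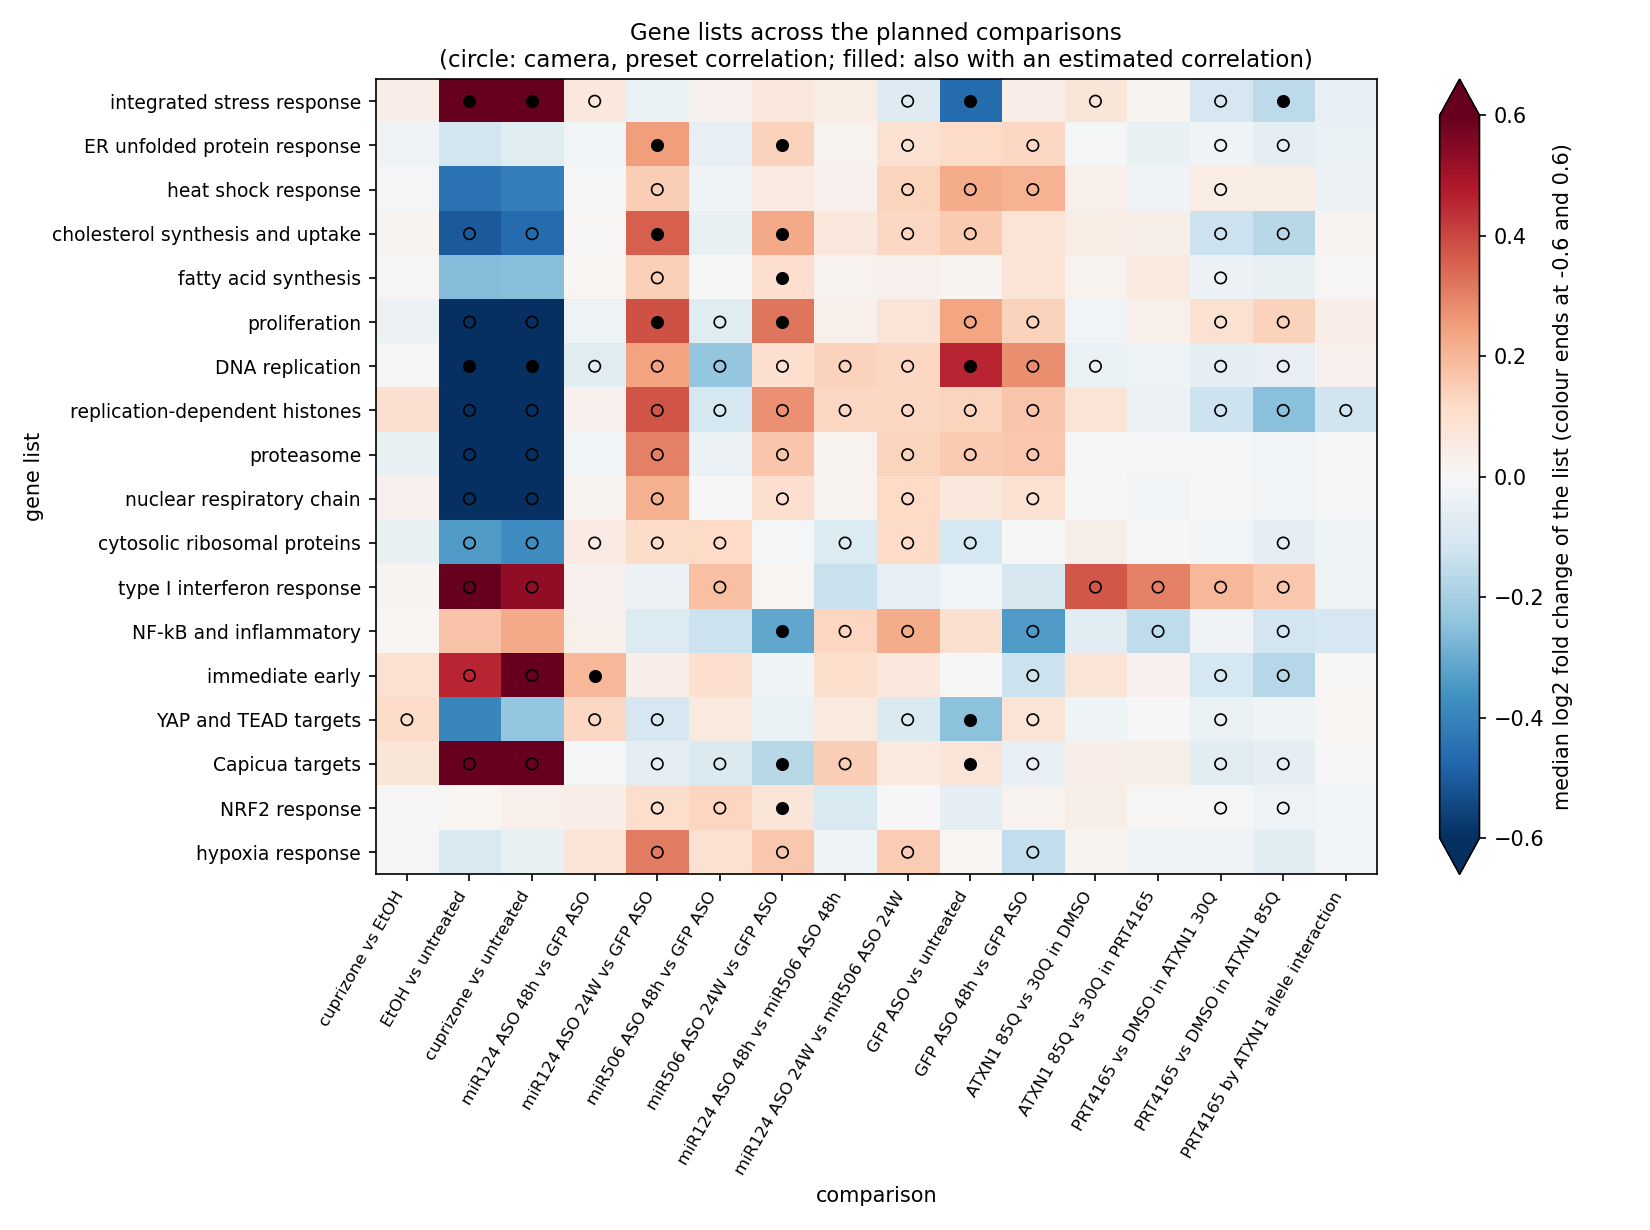
Median log2 fold change of 18 gene lists in each planned comparison (colour), with an open circle where camera passed at its preset correlation and a filled one where it also passed with an estimated correlation. Medians beyond the ends of the colour scale carry its end colours. The integrated stress response list ran from 1.95 in ethanol against untreated to -0.46 in the GFP ASO against untreated.

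The ASOs were compared with each other at each label, which also compares set 3 with set 4. At 48h WISP2 (-1.05 ± 0.16) was lower with the miR-124 ASO than with the miR-506 ASO (n = 3 against 3). HMGA1 (0.46 ± 0.08), PLAC8 (-0.45 ± 0.08) and CYP1B1 (-0.36 ± 0.07) had the smallest p of those that did not pass. SOX9 (-0.06 ± 0.18), PTBP1 (0.20 ± 0.07), CTDSP1 (0.21 ± 0.12) and LAMC1 (-0.05 ± 0.06) did not pass. By edgeR quasi-likelihood 2 genes passed, with 2315 below an unadjusted p of 0.05 where chance gives 875. WISP2 lost its call without single libraries, and the count was 1, 4 and 1 without miR-124 libraries 1, 2 and 3 and 16 without miR-506 library 2. It was 1 in a fit of the 2 groups alone, 38 by DESeq2 (19 higher, 19 lower) and 342 without a count filter (236 and 106).

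At 24W 15 genes were higher and 173 lower with the miR-124 ASO than with the miR-506 ASO (n = 3 against 3). The chemokines CXCL8 (0.85 ± 0.10), CXCL1 (0.45 ± 0.11) and CXCL5 (0.38 ± 0.08), the apoptosis inhibitor BIRC3 (0.38 ± 0.08) and the kinase SGK1 (0.35 ± 0.07) were higher. TMEM158 (0.47 ± 0.08), the protease ADAMTS1 (0.34 ± 0.07) and G0S2 (0.34 ± 0.08) were higher as well. The chromatin proteins ARID1A (-0.88 ± 0.19) and EP400 (-0.88 ± 0.20) and the transcription factors GLI3 (-1.06 ± 0.20), NFIC (-0.93 ± 0.22) and ZBTB20 (-0.91 ± 0.17) were lower. The scaffold MAGI2 (-0.92 ± 0.16), TP53INP2 (-0.92 ± 0.18) and the intronic N4BP2L2-IT2 (-0.95 ± 0.18) were lower too. Of 19 inflammation genes 3 rose, 6 adjusted over the list alone (median 0.22, camera adjusted p = 2.64e-09, adjusted p = 0.181 with an estimated correlation). Of 24 proteasome subunits 0 passed, 0 adjusted over the list alone (median 0.13, camera adjusted p = 1.79e-07, adjusted p = 0.298 with an estimated correlation). SOX9 (-0.36 ± 0.18), PTBP1 (0.01 ± 0.07), CTDSP1 (0.05 ± 0.12) and LAMC1 (-0.01 ± 0.06) did not pass. CXCL8 alone of 16 named genes kept its call without each library. The edgeR count was 1 without miR-124 library 1, 2 or 3 or miR-506 library 1 or 2, 357 without miR-506 library 3, 612 in a fit of the 2 groups, 331 by DESeq2 and 615 without a count filter. After the span and GC correction it was 466, with 213 higher and 253 lower.

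Genes with a site for the shared seed of both microRNAs in their 3' UTR were tested as a set, as a blocked microRNA would raise them. Over 2133 genes with a site and 10784 without, the difference of medians was -0.0101 (camera p = 0.185, not an exact test) for the miR-124 ASO at 48h. At 24W it was -0.0463 (p = 0.00558, not exact), which did not pass with an estimated correlation (p = 0.072). For the miR-506 ASO it was -0.0018 (p = 0.891, not exact) at 48h and -0.0102 (p = 0.556, not exact) at 24W. The fall at 24W with the miR-124 ASO was -0.0085 (p = 0.449, not exact) against genes matched on UTR length and GC content, and the other 3 differences lay above 0 in some settings. Of the 4 genes past the threshold with both ASOs at 48h, FOS and SCARNA15 among them, 0 carried a site.

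**Figure D4:**
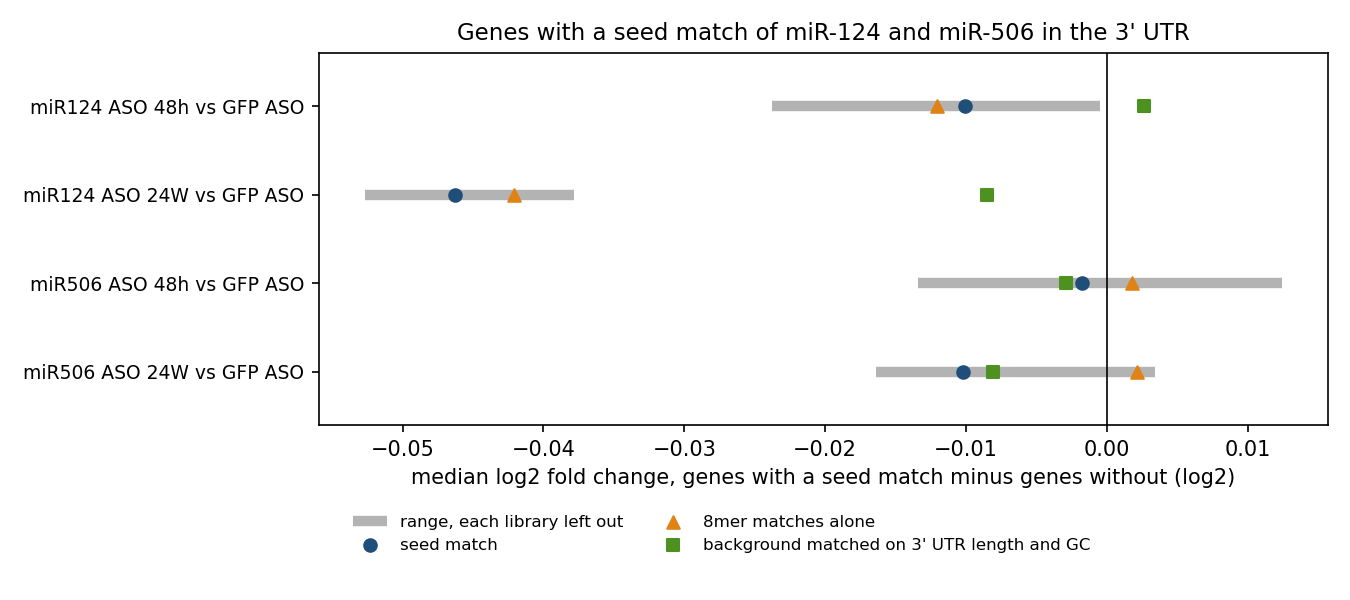
Difference of median log2 fold change between genes with and without a seed site in the 4 ASO comparisons, with the leave-one-out range, for all sites, for 8mer sites and against a matched background. The largest difference was -0.0463, with the miR-124 ASO at 24W.

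Both ASOs were compared with the same 4 GFP libraries, which makes their fold changes alike by construction. Both also carry a label, 48h or 24W, that these GFP libraries lack. At 24W 145 genes were higher and 82 lower with both, IDI1, IL1B, THSD4 and ZNF862 among them, and 1 went opposite ways. Independent lists would share 10.9 and 5.48, a count that leaves out the shared controls. Simulated data without an effect shared 0, but they held no changed genes to call, so this 0 is no baseline for the overlap. The fold changes correlated across genes at 0.43, in 20 simulations with shared controls alone at 0.43, and at 0.15 with the controls divided between the ASOs. The covariance was 0.0283 against a simulated 0.0154, a difference of 0.0129 (0.012 with divided controls). At 48h 3 higher genes and 1 lower gene were shared, where independent lists would share 0.0423 and 0.0107 and simulated data shared 0, with the same limits. The correlation was 0.45, simulated 0.43 and with divided controls 0.12, and the covariance 0.0249 against 0.0156 (difference 0.00931, and 0.00854 with divided controls).

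The labels 48h and 24W were compared within each ASO, a comparison added after the data were examined. Cholesterol and proliferation genes were lower at 48h than at 24W with both. With miR-124, of 24 cholesterol genes 18 fell, 21 adjusted over the list alone (median -0.34, camera adjusted p = 2.04e-25, adjusted p = 0.00288 with an estimated correlation). With miR-506, of 24 cholesterol genes 15 fell, 17 adjusted over the list alone (median -0.26, camera adjusted p = 4.77e-13, adjusted p = 0.024 with an estimated correlation). INSIG1 (-0.52 ± 0.07) and ACAT2 (-0.46 ± 0.07) fell with the former, LSS (-0.63 ± 0.10) and MVD (-0.55 ± 0.11) with the latter. With miR-124, of 21 proliferation genes 19 fell, 20 adjusted over the list alone (median -0.38, camera adjusted p = 3.8e-31, adjusted p = 0.0115 with an estimated correlation). With miR-506, of 21 proliferation genes 19 fell, 21 adjusted over the list alone (median -0.36, camera adjusted p = 1.53e-26, adjusted p = 0.024 with an estimated correlation). The mitotic kinesin KIF20A (-0.53 ± 0.06) and the mitotic kinase PLK1 (-0.66 ± 0.09) were examples. With the miR-124 ASO, of 14 YAP and TEAD targets 4 rose, 7 adjusted over the list alone (median 0.23, camera adjusted p = 7.66e-07, adjusted p = 0.021 with an estimated correlation). CTGF (0.47 ± 0.08) was higher at 48h. IL1B was higher at 48h with both (0.92 ± 0.15 and 1.08 ± 0.15, n = 3 against 3), and PTBP1 was lower with the miR-506 ASO (-0.25 ± 0.07). edgeR quasi-likelihood called 1286 genes for miR-124 (475 higher, 811 lower) and 1813 for miR-506 (882 and 931). These comparisons share no library, and 241 genes were higher and 343 lower in both, 0 opposite, where independent lists would share 23.9 and 43.1. The miR-124 count was 592, 503 and 567 without 24W libraries 1, 2 and 3 and 1997, 314 and 424 without 48h libraries 1, 2 and 3. For miR-124 it was 2315 in a fit of the 2 groups and 2300 after the span and GC correction (638 higher, 1662 lower). The miR-506 count was 728 and 924 without 24W libraries 1 and 2, 1141 without 48h library 3 and 367 in a fit of the 2 groups.

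The GFP ASO against untreated cells of set 4 asks what ASO treatment does without a human target. ANXA10 (1.39 ± 0.13), an annexin, ITGA2 (0.81 ± 0.10), a collagen receptor subunit, CXCL8 (0.75 ± 0.11), SERPINB2 (0.85 ± 0.15) and the cell cycle factor E2F2 (0.83 ± 0.16) rose (n = 4 against 2). NUPR1 (-1.69 ± 0.20), a stress-induced regulator, GDF15 (-1.33 ± 0.12), a stress cytokine, WISP2 (-1.40 ± 0.16) and the copy-rich PSG1 (-1.87 ± 0.17) and PSG5 (-1.21 ± 0.10) fell. Of 25 integrated stress response genes 20 fell, 22 adjusted over the list alone (median -0.46, camera adjusted p = 2.43e-46, adjusted p = 0.000867 with an estimated correlation). DDIT3 (-0.96 ± 0.09) and PPP1R15A (-0.75 ± 0.08) fell beside NUPR1 and GDF15. Of 14 YAP and TEAD targets 5 fell, 8 adjusted over the list alone (median -0.25, camera adjusted p = 1.61e-14, adjusted p = 0.00142 with an estimated correlation). ANKRD1 (-1.08 ± 0.08) fell. Of 20 DNA replication genes 16 rose, 18 adjusted over the list alone (median 0.46, camera adjusted p = 8.85e-28, adjusted p = 0.0469 with an estimated correlation). FEN1 (0.72 ± 0.12) and MCM4 (0.60 ± 0.10) rose. Of 19 Capicua targets 4 rose, 6 adjusted over the list alone (median 0.08, camera adjusted p = 0.000219, adjusted p = 0.0119 with an estimated correlation). SPRY2 (0.50 ± 0.09) rose. SOX9 (0.54 ± 0.19), PTBP1 (0.15 ± 0.08), CTDSP1 (0.10 ± 0.12) and LAMC1 (-0.11 ± 0.06) did not pass. edgeR quasi-likelihood called 520 genes (241 higher, 279 lower). The count was 296 and 330 without GFP libraries 1 and 2, 189 and 120 without untreated libraries 2 and 3, 797 by DESeq2 (446 higher, 351 lower) and 857 without a count filter (469 and 388), and E2F2 lost its call in some.

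The GFP ASO libraries labelled 48h (set 2) were compared with those of sets 3 and 4, so that time label and set go together (n = 4 against 4). PPME1 (0.75 ± 0.10), the Wnt antagonist DKK1 (0.63 ± 0.11), the collagen COL8A1 (0.57 ± 0.07), ZNF283 (0.54 ± 0.08) and the antisense EMC3-AS1 (0.58 ± 0.10) were higher at 48h. IL1B (-1.10 ± 0.18), THBD (-1.23 ± 0.17), the myosin MYO15B (-1.09 ± 0.15), the channel BEST1 (-1.44 ± 0.29) and the antisense VIM-AS1 (-0.95 ± 0.17) were lower. Of 19 inflammation genes 10 fell, 12 adjusted over the list alone (median -0.34, camera adjusted p = 6.19e-12, adjusted p = 0.277 with an estimated correlation). CXCL8 (-0.57 ± 0.05) and CXCL1 (-0.58 ± 0.08) fell beside IL1B. Of 15 heat shock genes 10 rose, 11 adjusted over the list alone (median 0.21, camera adjusted p = 1.24e-08, adjusted p = 0.277 with an estimated correlation). HSPH1 (0.34 ± 0.06) and HSPE1 (0.32 ± 0.06) rose. Of 13 fibroblast genes 5 fell, 7 adjusted over the list alone (median -0.30, camera adjusted p = 0.000137, adjusted p = 0.137 with an estimated correlation). COL5A1 (-0.56 ± 0.07) and COL6A2 (-0.36 ± 0.06) fell. edgeR quasi-likelihood called 1495 of 16167 genes (753 higher, 742 lower). The count was 293 (99 higher), 274 (110), 559 (215) and 2551 (1362) without set 2 libraries 1, 2, 3 and 4. It was 262 (86 higher), 427 (166) and 927 (318) without GFP libraries 2, 3 and 4, and 2523 without a count filter, and BEST1 lost its call in some.

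In set 5 the RNA of the plasmid gene ATXN1 (chromosome 6, 16299112 to 16761491) was read first. Its mean was 1230 ± 121 CPM in 30Q and 1830 ± 413 in 85Q with DMSO, and 806 ± 324 and 1120 ± 305 with PRT4165 (n = 3 each). Groups without plasmid stood at 10.5 to 35.6 CPM on total counts. The difference of 85Q from 30Q was 0.58 ± 0.22 in DMSO and 0.48 ± 0.22 in PRT4165, and that of PRT4165 from DMSO was -0.61 ± 0.22 in 30Q and -0.70 ± 0.22 in 85Q. None of the 4 passed, nor with the series of the titles as a block (adjusted p = 1, 1, 0.0727 and 0.0732), though all did without a count filter. Within the series 85Q lay above 30Q in 6 of 6 pairs of libraries and PRT4165 below DMSO in 6 of 6.

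85Q against 30Q asks what the longer glutamine repeat changes, and no gene passed in either treatment. The interferon-induced genes lay higher in 85Q. In DMSO, of 20 interferon genes 0 passed, 0 adjusted over the list alone (median 0.37, camera adjusted p = 2.86e-12, adjusted p = 0.441 with an estimated correlation). In PRT4165, of 20 interferon genes 0 passed, 0 adjusted over the list alone (median 0.30, camera adjusted p = 2.23e-16, adjusted p = 0.35 with an estimated correlation). IRF9 (0.76 ± 0.27) in DMSO and IFIT1 (0.68 ± 0.26) in PRT4165 had their smallest p. In PRT4165, of 19 inflammation genes 0 passed, 3 lower adjusted over the list alone (median -0.15, camera adjusted p = 1.63e-08, adjusted p = 0.35 with an estimated correlation). CXCL8 (-0.58 ± 0.09), CXCL1 (-0.57 ± 0.15), CXCL5 (-0.27 ± 0.07), C15orf48 (-0.36 ± 0.09) and the relaxin RLN2 (0.149 ± 0.046 in 30Q and 0.419 ± 0.0988 CPM in 85Q) had the smallest p there. In DMSO these were CXCL8 (-0.32 ± 0.09), CXCL5 (-0.29 ± 0.07), BIRC3 (-0.25 ± 0.06), ARL14EPL (-0.82 ± 0.20) and RN7SL4P (-2.37 ± 0.46), a copy of an abundant small RNA. On total counts without TMM, RN7SL4P stood at 370, 66.9 and 661 CPM in 30Q with DMSO. In 85Q it stood at 63.3 to 81.2, so libraries 1 and 3 carry its fold. Single libraries with ethanol (586) and the miR-506 ASO at 24W (418) were high too. The partners of ATXN1 and the ligase genes differed little in DMSO: CIC (0.02 ± 0.12), ATXN1L (-0.10 ± 0.08), RING1 (0.02 ± 0.07), RNF2 (0.07 ± 0.06) and BMI1 (0.00 ± 0.06). In PRT4165 they stood at 0.04 ± 0.12, 0.00 ± 0.08, -0.03 ± 0.06, 0.01 ± 0.06 and 0.06 ± 0.06. In DMSO, of 19 Capicua targets 0 passed, 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.307). edgeR quasi-likelihood called 0 of 15998 genes in DMSO (399 at an unadjusted p below 0.05) and 0 in PRT4165 (268, smallest adjusted p 0.0738), where chance gives 800. The main fit leaves the series of the titles in the spread, which can hide changes, so 0 calls do not show that no gene differed. DESeq2 called 0 and 1, and the fit without a count filter 13 and 18, and edgeR called 1 in DMSO without 30Q library 2. Over both treatments, a contrast added after the data were examined, CXCL8 alone passed (-0.45 ± 0.06, edgeR adjusted p = 0.0213). Over both, of 20 interferon genes 0 passed, 10 higher adjusted over the list alone (median 0.34, camera adjusted p = 2.74e-22, adjusted p = 0.292 with an estimated correlation). DESeq2 called 3 genes over both and the fit without a count filter 43. The count over both was 0 without library 1 of any group or library 3 of 30Q with DMSO or 85Q with PRT4165, and 2 without library 3 of 30Q with PRT4165. CXCL8 also lost its call without library 2 of 30Q with DMSO, where 1 other gene passed.

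PRT4165 against DMSO asks what blocking the Polycomb ligase changes. In 30Q 1 gene passed, MTND1P23 (1.12 ± 0.16), a nuclear copy of a mitochondrial gene that shares reads with it. MTND2P28 (0.94 ± 0.16), another such copy, C15orf48 (0.55 ± 0.09), S100A6 (0.31 ± 0.06), a calcium-binding protein, and RN7SL4P (-2.53 ± 0.47), whose fold the same 2 libraries carry, had the next smallest p. In 85Q none passed. RCAN1 (-0.69 ± 0.12), an inhibitor of calcineurin, TXNIP (-0.53 ± 0.12), which binds thioredoxin, MTND1P23 (0.96 ± 0.16), MTND2P28 (0.77 ± 0.16) and DPY19L2P2 (0.66 ± 0.14) had the smallest p. In 30Q, of 25 integrated stress response genes 0 passed, 7 lower adjusted over the list alone (median -0.10, camera adjusted p = 1.09e-10, adjusted p = 0.101 with an estimated correlation). In 85Q, of 25 integrated stress response genes 0 passed, 7 lower adjusted over the list alone (median -0.16, camera adjusted p = 1.13e-17, adjusted p = 0.0455 with an estimated correlation). ATF3 (-0.46 ± 0.10) and PPP1R15A (-0.28 ± 0.06) had their smallest p. In 85Q, of 24 cholesterol genes 0 passed, 0 adjusted over the list alone (median -0.17, camera adjusted p = 1.65e-12, adjusted p = 0.209 with an estimated correlation). In 85Q, of 44 developmental regulators silenced by Polycomb 0 passed, 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.996). In 30Q, of 44 developmental regulators silenced by Polycomb 0 passed, 0 adjusted over the list alone (median 0.00, camera adjusted p = 0.429). In 85Q, of 25 Polycomb group genes 0 passed, 0 adjusted over the list alone (median -0.02, camera adjusted p = 0.376). RING1 (0.05 ± 0.07 in 30Q and 0.00 ± 0.07 in 85Q), RNF2 (0.00 ± 0.06 and -0.07 ± 0.06), BMI1 (-0.06 ± 0.06 and 0.01 ± 0.06), CIC (-0.02 ± 0.12 and 0.00 ± 0.12) and ATXN1L (-0.05 ± 0.08 and 0.05 ± 0.08) did not pass. edgeR quasi-likelihood called 1 gene in 30Q (423 at an unadjusted p below 0.05) and 0 in 85Q (577, smallest adjusted p 0.229), where chance gives 800. Here too the series of the titles stays in the spread of the main fit and can hide changes. DESeq2 called 8 and 2, the fit without a count filter 35 and 62 (10 higher and 52 lower in 85Q), and the 30Q count 2 in a fit of the 2 groups alone. The 30Q count was 0 without any library of the 2 groups but DMSO library 2, where 1 lower gene passed and MTND1P23 did not.

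Over both alleles, a contrast added after the data were examined, 11 genes passed with PRT4165 (n = 6 against 6). MTND1P23 (1.04 ± 0.11), MTND2P28 (0.85 ± 0.12), MTND5P11 (0.54 ± 0.09), all nuclear copies of mitochondrial genes, S100A6 (0.25 ± 0.04) and C15orf48 (0.39 ± 0.07) rose. TXNIP (-0.52 ± 0.09), TXNRD1 (-0.27 ± 0.05), the stress factors ATF3 (-0.41 ± 0.07) and PPP1R15A (-0.26 ± 0.05), ZNF404 (-0.31 ± 0.05) and ZNF283 (-0.29 ± 0.05) fell. All 11 are named, those outside the naming rule chosen after the values were seen. Over both, of 25 integrated stress response genes 2 fell, 10 adjusted over the list alone (median -0.13, camera adjusted p = 4.27e-20, adjusted p = 0.029 with an estimated correlation). The count was 41 by DESeq2 and 126 without a count filter (32 higher, 94 lower). It was 1 without library 1 of 85Q with PRT4165 or 30Q with DMSO, 2 without library 1 of 85Q with DMSO, 2 of either PRT4165 group or 3 of 30Q with DMSO, 4 without library 2 of either DMSO group and 5 without library 3 of 85Q with DMSO. Without library 1 of 30Q with PRT4165 it stayed 11, with 6 of the genes shared. The interaction, which asks whether the response to PRT4165 differs between 85Q and 30Q, gave 0 genes by edgeR quasi-likelihood (177 at an unadjusted p below 0.05), 0 by DESeq2, 7 without a count filter and 1 without library 2 of 30Q with DMSO. MFNG (2.53 ± 0.60), RN7SL4P (2.37 ± 0.64), again by 2 libraries, SLC25A34 (1.85 ± 0.55), PDE2A (-0.82 ± 0.22) and RSPO4 (-1.56 ± 0.46) had the smallest p. ATXN1 differed by -0.10 ± 0.31, CIC by 0.02 ± 0.17, ATXN1L by 0.10 ± 0.12, RING1 by -0.05 ± 0.09, RNF2 by -0.07 ± 0.09 and BMI1 by 0.06 ± 0.08, none past the threshold.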

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

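The tests of library depth, of the span of the lower genes and of the slope on ATXN1, and the comparisons of 48h with 24W and over both alleles or both treatments, were chosen only after their results were seen.

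Ethanol and cuprizone libraries differed from the untreated libraries of set 1 in most genes (11211 and 10943). A difference in depth is argued against by a ratio of mean total counts of 0.95, ethanol over untreated. Untreated libraries of set 1 that are themselves out of place cannot be told apart from a change by the treatments: for 46.3% of the genes past the threshold (48.1% for cuprizone) they lay farther from the untreated libraries of set 4 than the treated ones did. Their median distance to set 4 was 0.46, that of ethanol 0.51, and the mean correlations with set 4 were 0.9707 (untreated), 0.9537 (ethanol) and 0.9574 (cuprizone). A response to the solvent, which both treatments may share, stays open and untested.

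The miR-124 ASO libraries at 24W lay below those of the miR-506 ASO in 173 of 188 genes, most of them long. A smooth trend over gene span and GC content between libraries is argued against as the whole cause of the lower values in these genes. After its correction their median went from -0.63 to -0.58 (median standard error 0.14 and 0.13). Of the genes with known values 93.5% (173 kept of 185) stayed past the threshold. This share alone decides little, as the corrected fit called 466 genes and so had an easier cut. A bias that acts on some long genes only was not tested. The count of 188 itself ran from 1 to 357 when single libraries were left out. After the correction 213 genes were higher and 253 lower, against 15 and 173 before. It re-centres each library over span and GC content, so this balance decides nothing about the cause. Gene span does mark them: the lower genes had a median span of 87.7 kb against 23.8 kb for other genes, a ratio of 3.68, and the higher ones 8.32 kb. Long genes were not particular to this comparison. Against the GFP ASO the lower genes at 24W spanned 55.6 kb with miR-124 and 49.1 kb with miR-506. Other genes there spanned 23.7 and 23.9 kb. Genes higher at 48h than at 24W spanned 50.5 kb with miR-124 and 47.4 kb with miR-506. A biological explanation was not tested, and set 3 and set 4 go with the ASO here, so a difference between the sets stays open.

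The interferon list lay higher in 85Q than 30Q. Within groups libraries with more ATXN1 had lower list scores (Pearson r = -0.84, Spearman rho = -0.83, 2-sided exact permutation p = 0.0131 over 12 libraries and 1296 permutations). Without the 2 libraries farthest from the median r was -0.88. This test ignored the series of the titles, and library 3 of every group had the most ATXN1 and the lowest score, so its planned bound of 0 was wrong. With group and series removed r was -0.5, and the slope of the list score on ATXN1 was -0.40 ± 0.32 (-0.91 to 0.05 without single libraries). A part played by plasmid RNA therefore cannot be told apart from none, with 12 libraries. As the whole cause it is argued against, though narrowly, as the slope needed was 0.69 ± 0.24 (t = 2.76 with 5 degrees of freedom, limit 2.57). This t took the errors of both slopes as independent, though they come from the same libraries, and was not recomputed without single libraries. A single series of the titles as the cause is argued against, as the difference was above 0 in 6 of 6 pairs of libraries of a series (DMSO 0.37, 0.37 and 0.34, PRT4165 0.01, 0.46 and 0.68). An effect of the longer repeat stays a hypothesis, with an adjusted p of 0.441 and 0.35 in DMSO and PRT4165 with an estimated correlation.

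A difference between the ASOs was called at 48h for 2 genes, WISP2 (-1.05) among them, and at 24W for 188 genes, CXCL8 (0.85) among them. Between the labels 48h and 24W 1286 genes differed with the miR-124 ASO and 1813 with the miR-506 ASO. In the GFP ASO group of sets 3 and 4, THSD4 stood at 22.6 CPM in replicate 4 and at 19.2 to 19.6 in the others, a gap of 0.903 of the range. It was 1 of 79 groups tested, where chance gives 1 in 20.

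Other splits of the same libraries were counted for each comparison but the GFP ASO against untreated, which has 2 untreated libraries. Chance is argued against for the miR-124 ASO at 24W, where 1 split of 35, the real one, gave as many genes (real 1722, highest other 837). As much was seen for the miR-506 ASO at 48h (242 and 21) and at 24W (327 and 170). This share lies under 0.05 but is the smallest that 35 splits can give, and it was not adjusted over the comparisons. Chance cannot be excluded for the miR-124 ASO at 48h (2 splits of 35, 7 and 97), where a split called several times the real count, which points to a structure of the samples. Nor can it for the GFP ASO groups (2 splits of 35, 1495 and 1536), where the other split joined GFP ASO library 1 to set 2 libraries 1, 2 and 3. The same holds for PRT4165 over both alleles (3 splits of 40, 11 and 82) and 85Q against 30Q over both treatments (6 splits of 40, 1 and 10), both again with more genes in a split than in the real one. For the interaction (0 and 1 over 40 splits) and other comparisons with a real count of 0 the splits decide nothing. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real and highest other counts were 5 and 370 for cuprizone against ethanol (3 splits as large, and a structure of the samples again), 11211 and 0 for ethanol and 10943 and 1 for cuprizone against untreated. They were 2 and 102 (2 splits as large) and 188 and 0 for miR-124 against miR-506 at 48h and 24W, and 1286 and 0 and 1813 and 89 for 48h against 24W. In set 5 they were 0 and 0 for 85Q against 30Q in DMSO, in PRT4165 and for PRT4165 in 85Q (all 10 splits as large), and 1 and 0 for PRT4165 in 30Q.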

How the results depend on the processing

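The contrasts over both alleles or both treatments, the comparisons of 48h with 24W and the correction for gene span and GC content were chosen after seeing the data, and the other alternatives before. RLE scaling left all 20 counts within 1.5 times. The named genes gave 798 called pairs of a gene and a comparison. Of their 9408 values under the alternatives 8066 stayed past the threshold, 1339 fell short of it with the direction unchanged and 3 turned. Of the values of pairs not called 979 stayed so, 59 passed and 65 turned. The cause was not tested for any change below, except that fits without single libraries have fewer samples. Genes with few counts were measured less closely: the median standard error of a log2 fold change was 0.24 to 0.49 over the comparisons in the lowest quartile of genes by level and 0.04 to 0.09 in the highest. Depth itself was not varied.

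Without a filter on low counts the counts were 238 for cuprizone against ethanol, 89 and 826 for the miR-124 and miR-506 ASO at 48h, 574 for the miR-506 ASO at 24W, 342 and 615 for miR-124 against miR-506 at 48h and 24W, 857 for the GFP ASO against untreated and 2523 between the GFP ASO groups. In set 5 they were 13 and 18 for 85Q against 30Q in DMSO and PRT4165, 35 and 62 for PRT4165 in 30Q and 85Q, 7 for the interaction, 126 for PRT4165 over both alleles and 43 for 85Q over both treatments. PTBP1 in miR-124 against miR-506 at 24W turned to -0.0024, and ATXN1L and RNF2 in 85Q against 30Q in PRT4165 to -0.0047 and -0.0031. DESeq2 called 19, 15, 711, 554, 38, 331 and 797 genes for cuprizone against ethanol, the miR-124 ASO at 48h, the miR-506 ASO at 48h and 24W, miR-124 against miR-506 at 48h and 24W and the GFP ASO against untreated, and in set 5 1 for 85Q in PRT4165, 8 and 2 for PRT4165 in 30Q and 85Q, 41 for PRT4165 over both alleles and 3 for 85Q over both treatments.

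With the set 2 GFP libraries as control the counts were 2117 for the miR-124 and 5086 for the miR-506 ASO at 48h. SOX9 turned to 0.13 with the former, and SOX9 (0.18), SH3TC2 (0.0053), ANKRD1 (-0.037) and TXNRD1 (-0.036) with the latter. A fit of the compared groups alone gave 3274 for the miR-124 ASO at 24W, 11 for the miR-506 ASO at 48h, 1 and 612 for miR-124 against miR-506, 2 for PRT4165 in 30Q, and 2315 and 367 for 48h against 24W with miR-124 and miR-506, and PTBP1 at 24W turned to -0.0097 between the ASOs. After the span and GC correction there were 2978 and 664 genes for the miR-124 and miR-506 ASO at 24W, 466 between them (213 higher, 253 lower) and 2300 for 48h against 24W with miR-124. LAMC1 turned to 0.0065 with the miR-124 ASO at 24W and to 0.052 between the ASOs, where PTBP1 turned to -0.0064. With an estimated correlation 21 list tests of the planned comparisons passed.

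The difference of medians of seed site genes was 0.0026 for the miR-124 ASO at 48h and -0.0085 at 24W against the matched background, and the latter, at -0.0463, no longer passed with an estimated correlation. For 8mer sites it was 0.0018 and 0.0021 for the miR-506 ASO at 48h and 24W. When each library was left out it ran from -0.024 to -0.0005 for the miR-124 ASO at 48h, the lowest without its library 2 and past the threshold, from -0.013 to 0.012 for the miR-506 ASO at 48h and from -0.016 to 0.0034 at 24W.

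With each library left out in turn, the lowest and highest counts were 4 and 158 for cuprizone against ethanol, 4 and 7 and 666 and 1839 for the miR-124 ASO at 48h and 24W, 51 and 590 and 120 and 426 for the miR-506 ASO, 1 and 16 and 1 and 357 between them, 120 and 551 for the GFP ASO against untreated and 262 and 2551 between the GFP ASO groups. For 48h against 24W they were 314 and 1997 with miR-124 and 728 and 2062 with miR-506. In set 5 they were 0 and 1 for 85Q against 30Q in DMSO, PRT4165 in 30Q and the interaction, 1 and 14 for PRT4165 over both alleles and 0 and 2 for 85Q over both treatments. Ethanol and cuprizone against untreated stayed within 10174 and 11023.

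Genes that were not called and turned without single libraries were the following. For the miR-124 ASO at 48h the range was -0.070 to 0.034 for CTDSP1 and -0.049 to 0.049 for PTBP1, and for the miR-506 ASO at 24W -0.0004 to 0.10 for PTBP1. Between the ASOs it was -0.090 to 0.0059 for LAMC1 and -0.38 to 0.12 for SOX9 at 48h, and -0.0084 to 0.11 for CTDSP1, -0.032 to 0.012 for LAMC1 and -0.030 to 0.037 for PTBP1 at 24W. For 85Q against 30Q it was -0.041 to 0.041 for BMI1, -0.11 to 0.10 for CIC and -0.034 to 0.078 for RING1 in DMSO, and -0.047 to 0.067 for ATXN1L, -0.043 to 0.13 for CIC, -0.070 to 0.019 for RING1 and -0.045 to 0.049 for RNF2 in PRT4165. For PRT4165 it was -0.089 to 0.0041 for ATXN1L, -0.14 to 0.057 for CIC, -0.0055 to 0.11 for RING1 and -0.016 to 0.011 for RNF2 in 30Q, and -0.028 to 0.14 for ATXN1L, -0.012 to 0.024 for BMI1, -0.084 to 0.089 for CIC and -0.044 to 0.045 for RING1 in 85Q. For the interaction it was -0.34 to 0.28 for ATXN1, -0.063 to 0.14 for CIC and -0.11 to 0.0072 for RING1.

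A replicate block gave 1147 genes for the miR-124 ASO at 24W, 583 for the miR-506 ASO at 48h, 2954 between the GFP ASO groups, 2 for PRT4165 in 30Q, 2 for 85Q over both treatments and a seed site difference of 0.009 for the miR-506 ASO at 48h. Of pairs with the same number, a correlation over 0.1 was seen in 1 of 4, 2 of 9 and 4 of 40 in the GFP, set 1, and sets 3 and 4 fits (lowest -0.054, -0.054 and -0.119, highest 0.137, 0.216 and 0.182), so the numbers pair few libraries there. In set 5 the number is the series of the titles, and it was seen in 7 of 18 (-0.071 to 0.253, mean 0.068 against -0.034 for other pairs). The libraries numbered 3 lay at -20.38 to -1.78 on PC1 and the others at -3.19 to 15.84, ranges that overlap. The main fit leaves the series in the spread.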

Other observations

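Markers of brain cell types were read in the set 1 comparisons, as values of lists fixed before the data were examined. With ethanol against untreated, of the 5 tested oligodendrocyte lineage genes, from a list of 22, 3 rose and 1 fell. The count filter left out the other members of the cell type lists. Among them were OLIG2 (mean 0.00367 CPM over all libraries), GFAP (0.0679) and AQP4 (0) of astrocytes and RBFOX3 (0.0116) of neurons. PDGFRA (3.08 ± 0.22), the growth factor receptor of progenitors, rose from 0.6 ± 0.116 to 5.09 ± 0.759 CPM (n = 3 against 3), CNTN1 (0.62 ± 0.09), an adhesion protein, rose, and the lineage factor ZNF488 (-1.77 ± 0.17) fell. Of 7 tested astrocyte markers, from a list of 14, 4 rose, 4 adjusted over the list alone (median 0.60, camera adjusted p = 0.0125, adjusted p = 0.154 with an estimated correlation). CLU (1.80 ± 0.08), a secreted chaperone, SLC1A3 (1.78 ± 0.13), a glutamate transporter, and FGFR3 (1.73 ± 0.12) rose. Of 8 tested neuron markers, from a list of 21, 6 rose, 6 adjusted over the list alone (median 0.96, camera adjusted p = 0.0404, adjusted p = 0.223 with an estimated correlation). SYT1 (2.05 ± 0.13) and SYP (1.30 ± 0.18) of synaptic vesicles and GAD1 (0.77 ± 0.08), which makes GABA, rose. Of 18 p53 response genes 9 rose and 3 fell, 9 and 3 adjusted over the list alone (median 0.26, camera adjusted p = 0.105). GDF15 (3.75 ± 0.19) and the cell cycle inhibitor CDKN1A (1.52 ± 0.11) rose, and AEN (-1.58 ± 0.08) fell. Of 36 ribosomal protein genes 36 fell, 36 adjusted over the list alone (median -0.34, camera adjusted p = 0.000972, adjusted p = 0.528 with an estimated correlation). RPL15 (-0.59 ± 0.05) and RPS3 (-0.41 ± 0.05) were among them. A fall of this size depends on the TMM factors, 1.0529 to 1.0606 with ethanol and 0.8811 to 0.8832 in untreated set 1.

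CYP1B1, CYP1A1 and TIPARP, all known targets of the aryl hydrocarbon receptor, were grouped after their values were seen. On total counts without TMM, CYP1B1 stood at 210 ± 14.2 CPM with ethanol, 116 ± 6.27 with cuprizone and 33.5 ± 0.197 in untreated set 1. CYP1A1 stood at 12.1 ± 1.46, 5.26 ± 0.211 and 4.07 ± 0.799. TIPARP stood at 381 ± 11.2, 277 ± 20.3 and 190 ± 10. The fall of these 3 with cuprizone was thus a fall from levels that lay above untreated with ethanol. Other known targets did not fall alike: AHRR stood at 12.4 ± 0.356, 12.8 ± 0.0458 and 11.2 ± 0.3, and NQO1 at 174 ± 7.05, 154 ± 6.41 and 128 ± 3.19. No fixed list of targets was tested.

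On chromosome 1 from 629062 to 634922 lie 7 nuclear copies of mitochondrial genes. Over both alleles with PRT4165, MTND1P23 (1.04 ± 0.11, edgeR adjusted p = 0.00105) and MTND2P28 (0.85 ± 0.12, adjusted p = 0.00933) rose. MTCO1P12 (-0.21), MTCO2P12 (0.06), MTATP8P1 (0.37), MTATP6P1 (0.14) and MTCO3P12 (-0.22) did not pass. All 7 resemble mitochondrial genes, which stood at 0 counts in all libraries, and reads shared with those leave them uncertain.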
